A study of Homo sapiens with 6 samples.

How the data were processed

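RNA abundance was measured by bulk RNA sequencing in 6 libraries of Jurkat cells, an established human T-cell leukemia line, made with a TruSeq kit from total RNA. Per the labels, 3 libraries came from cells overexpressing PDCD1^28, a splicing isoform of the gene of the PD-1 receptor, and 3 from cells with the vector. The growth protocol calls the cells Jurkat KO-1, and the labels used here do not say what the addition means. The labels number the libraries of each group but do not say that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

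The deposited table held whole-number expected counts, that is estimated counts, for 59248 gene symbols in 1 column per library, and the values were not scaled to a common total. Per the submitters' processing notes, fastp 0.23.2, STAR 2.7.10a, StringTie and DESeq2 were used with build hg38; the annotation release and the strand setting were not given in the sources used here. Among the lowest deposited values, an estimated count of 4 was more frequent than 3 in each column, and 8 more frequent than 7 in each but that of vector replicate 2, as if 1 read pair added about 4. A value of 1 was the most frequent above 0 in each column, with 2716 to 3651 genes, which such a unit does not give, so the unit is not settled. Total estimated counts ran from 59911578 to 84220970 per library, and because of this unit no interval that treats 1 estimated count as 1 read is given. The floor was set at 3 read pairs, taken as 12 estimated counts per library on that reading, and covers counting error only; if 1 read pair adds less, the floor is lower and the bounds on folds are larger.

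Genes were kept by the default expression filter of edgeR 4.0.16 (R 4.3.3), scaled by TMM factors and compared by the quasi-likelihood F test with group as the only term. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05, and standard errors of log2 fold changes were derived from the same F statistic. CPM values are estimated counts scaled by the TMM-adjusted library size. The fit was tested on simulated counts for 20392 genes of the same 6 libraries. It recovered 50% of genes changed 1.5-fold, 74% of those changed 2-fold and 88% of those changed 4-fold. These genes were drawn from those with a mean above a set minimum. There were 15 false calls among 285. The S phase list and the genes of chromosome 13 were shifted as well, and their calls are among the 285. Far fewer genes were called there than in the data, so these shares need not hold for the data.

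For 34 gene lists, camera from limma 3.58.1 was run with a preset correlation between genes of 0.01, and again with an estimated correlation; fry tested whether the genes of a list moved on balance one way. PDCD1 was left out of the lists. The lists, the main test, the naming rule and the first set of alternative settings were fixed before the data were examined. The rule named PDCD1, CD274 and PDCD1LG2 in any case, then the 8 largest fitted rises and the 8 largest falls among called genes with a mean of at least 100 estimated counts, a proper symbol and groups that did not overlap, and from each list up to 2 risen and 2 fallen members with the smallest adjusted p. A list with no called member was to be given by at most 2 members of highest mean. Some genes that this rule names are not reported here.

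Shares of counts were compared by an exact two-sided permutation test, for which 3 libraries against 3 cannot give a p below 0.1. Positions, GC content and transcript length came from GENCODE 29 on GRCh38, the assembly that hg38 names; 40041 of the 59248 symbols matched. Changes along chromosomes were summarised over 11688 protein-coding genes with a mean of at least 100 estimated counts, in windows of at least 40 consecutive genes, after the results per gene had been seen. A window was called shifted when its median log2 change was at least 0.3 from 0.

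This first set held DESeq2 1.42.0, limma-voom, DESeq2 size factors or upper-quartile factors in edgeR, no filter, a stricter filter (mean of at least 1 CPM and 50 estimated counts), the replicate number as a block, each library left out in turn, the estimated correlation and a size threshold of 2-fold. Division of the values by 4, removal of genes of chromosomes 2 and 9 and of shifted blocks elsewhere (called removal of chromosome blocks) and removal of a per-library trend on GC content and length were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.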

Results

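Transcript abundance was compared between 3 libraries of Jurkat cells overexpressing the PD-1 isoform PDCD1^28 and 3 vector libraries. The overexpression libraries held 62635749, 72314037 and 61486369 estimated counts and the vector libraries 59911578, 84220970 and 69825013. The first principal component, with 61.8% of the variance, separated the groups, and the second, with 12.1%, set vector replicate 2 apart from the other vector libraries. The comparison addressed which transcripts differ when the isoform is overexpressed.

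PDCD1, which encodes the inhibitory receptor PD-1, was 60-fold higher in overexpression, at 13.8 ± 1.03 CPM against 0.229 ± 0.011 CPM in vector (SD, n = 3 each; log2 fold change 5.91 ± 0.17, SE; edgeR adjusted p = 5.7e-07). Its estimated counts were 945, 1059 and 807 in overexpression and 14, 18 and 15 in vector. The vector values lie near the floor of 12, so the size of the fold is less certain than its SE. The values are per gene on chromosome 2 (241849881 to 241858908, minus strand, hg38) and do not separate the isoform from other PDCD1 transcripts. CD274, which encodes the PD-1 ligand PD-L1 (chromosome 9, 5450503 to 5470566), rose 2.91-fold, from 0.453 ± 0.204 to 1.33 ± 0.162 CPM (edgeR adjusted p = 0.0092). PDCD1LG2, the gene of the other ligand, had 1, 0 and 0 estimated counts in either group, at or under the floor of 12, and was not tested.

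CD28, CD40LG and ZBTB16 were among the largest falls, and ABCC8, BST2 and CALB2, at under 1 CPM in vector, among the largest rises. CD28, the costimulatory receptor, fell from 218 ± 47.9 to 1.90 ± 0.381 CPM, and CD40LG, the CD40 ligand, from 47.5 ± 20.1 to 0.173 ± 0.103 CPM (SD, n = 3). The transcription factor gene ZBTB16 fell from 41.5 ± 2.09 to 0.443 ± 0.00435 CPM. ZNF726 had a log2 fold change of -7.45 ± 0.74 (SE) and CYTIP of -7.01 ± 0.95; both genes lay near 0 in overexpression. Without overexpression replicate 3 the fitted change of CYTIP was -10.89, without overexpression replicate 2 it was -6.40, and without overexpression replicate 1 that of ZNF726 was -9.25. BLK, a Src-family kinase gene, had no counts in overexpression against 7.02 ± 1.14 CPM in vector, at least 39.5-fold lower against the floor per library. SIGLEC6 had no counts in overexpression either and was at least 35.1-fold lower, or at least 13.4-fold lower without vector replicate 2.

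ABCC8, which encodes a subunit of potassium channels, had the largest fitted rise among the genes named by size of change, from 0.121 ± 0.0939 to 19.8 ± 2.23 CPM, with a log2 fold change of 7.42 ± 0.46 (SE), or 6.80 without vector replicate 2. BST2, an interferon-induced restriction factor gene, rose from 0.405 ± 0.239 to 26.3 ± 1.14 CPM. CALB2, which encodes the calcium-binding protein calretinin, rose from 0.0395 ± 0.0356 to 2.96 ± 0.179 CPM. The cancer-testis antigen genes MAGEA1, CTAG2 and MAGEB2 had log2 fold changes of 6.33 ± 0.53, 5.87 ± 0.70 and 5.76 ± 0.33. These antigen genes share sequence with close paralogs, and their levels are uncertain to that extent. In vector, ABCC8 had 10, 1 and 12 estimated counts, CALB2 had 4, 4 and 0, and MAGEA1 had 0, 5 and 4. These values lie at or under the floor of 12, so the sizes of the rises of ABCC8, CALB2 and MAGEA1 are uncertain. For CTAG2 the change was 6.51 without vector replicate 1, 5.20 without vector replicate 2 and 8.01 with limma-voom; vector replicate 2 had 0 counts of this gene.

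**Figure D1:**
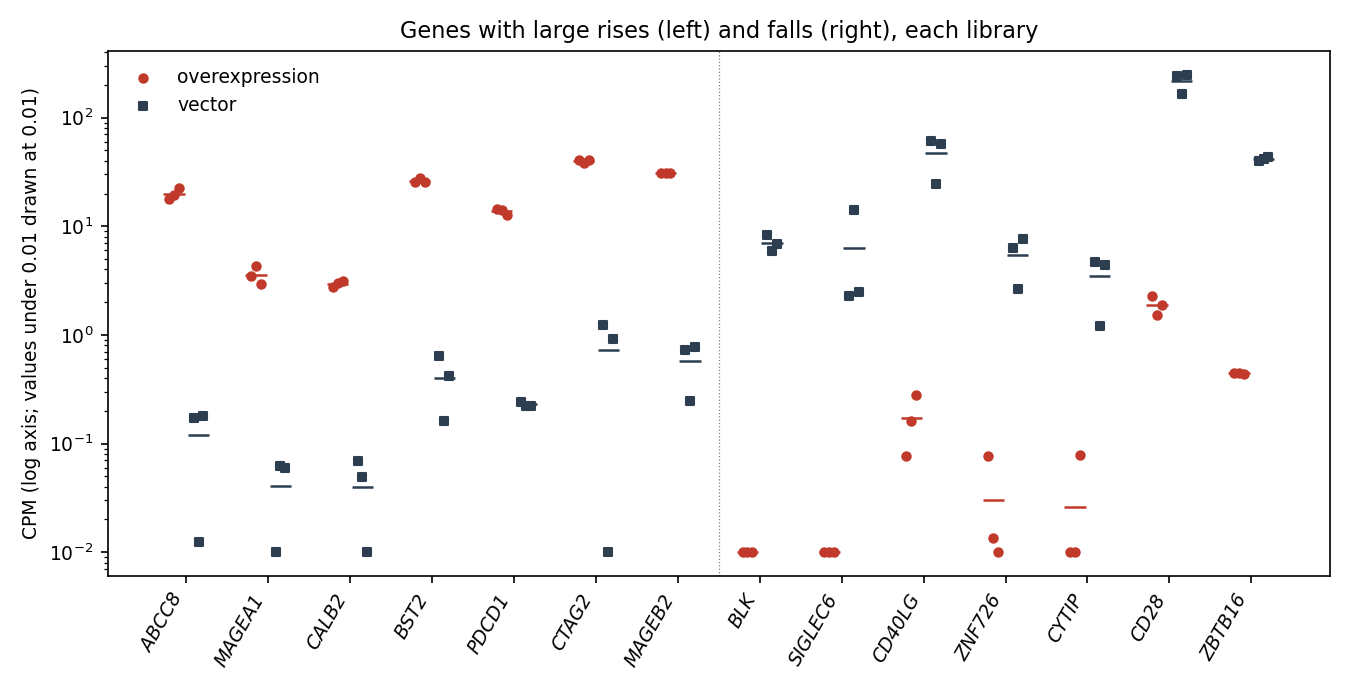
CPM on a log axis of 7 of the 8 genes with the largest rises and 7 of the 8 with the largest falls by the naming rule; circles are overexpression libraries, squares vector libraries, short lines group means of 3 libraries, and values under 0.01 are drawn at 0.01. PDCD1 lies at or above 12.6 CPM in overexpression and at or below 0.242 CPM in vector, and BLK and SIGLEC6 have no counts in overexpression.

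In all, 9705 of 21055 genes tested passed the edgeR threshold (46.1%), 4768 of them higher and 4937 lower in overexpression. A fitted change of at least 2-fold was held by 1766 of the higher and 1310 of the lower genes, or 1090 and 814 under the stricter filter, which tested 14917 genes. In 12356 genes (58.7%) the libraries of the groups did not overlap, where chance gives 10%.

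Most genes of the ATF4 and amino acid response rose and most heat shock genes fell; with an estimated correlation the heat shock list kept its camera call (adjusted p = 0.0242) and the ATF4 list did not (adjusted p = 0.0513). Of 31 ATF4 list members tested, 27 rose and 1 fell, with a median log2 fold change of 1.13. PHGDH, which encodes the first enzyme of serine synthesis, rose from 211 ± 6.54 to 678 ± 20.04 CPM, and TRIB3, a pseudokinase gene induced by ATF4, from 43.9 ± 5.02 to 224 ± 2.67 CPM (SD, n = 3). DDIT4 was the member that fell, by 0.43 on the log2 scale. The camera test gave an adjusted p = 1.95e-30 with the preset correlation. Of 20 heat shock genes, 16 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -1.01. HSPA8, a constitutive HSP70 chaperone gene, fell from 1892 ± 22.4 to 409 ± 9.54 CPM and HSPH1 from 192 ± 3.45 to 37.8 ± 0.700 CPM, while HSPB1 rose with a log2 fold change of 0.79 ± 0.08 (SE). This list alone kept its call with an estimated correlation (adjusted p = 8.7e-33 with the preset one). For the activation, checkpoint, interferon and unfolded protein response lists the estimated correlations were -0.0111, -0.0411, -0.0138 and -0.011, under the preset 0.01. Their losses of call, given below, were therefore not due to a higher correlation between genes. So the preset and estimated forms of the test differed in more than the correlation. In the other called lists the estimate was above 0.01, from 0.0327 to 0.679. How far this accounts for the losses of call among them was not tested.

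T-cell receptor and activation genes were mostly lower. In the list of the TCR complex and proximal signalling, 26 of 38 members fell and 6 rose (27 and 7 adjusted over the list alone; median -0.61; camera adjusted p = 1.3e-08; adjusted p = 0.142 with an estimated correlation). Besides CD28, the adaptor gene GRAP2 fell, from 151 ± 16 to 31.1 ± 1.37 CPM, while TRBC1, a TCR beta constant gene, and CSK, a kinase gene that restrains TCR signalling, rose with log2 fold changes of 0.42 ± 0.05 and 0.33 ± 0.05. Of 29 activation and immediate early genes, 18 fell and 1, NR4A1, rose (median -0.83; adjusted p = 3.5e-05; adjusted p = 0.0802 with an estimated correlation). JUND had a log2 fold change of -1.57 ± 0.07 and NR4A1 of 0.67 ± 0.13. Of 32 cytokine, chemokine and receptor genes, 18 fell and 4 rose (19 and 4 adjusted over the list alone; median -0.83; adjusted p = 6.6e-05; adjusted p = 0.393 with an estimated correlation). CCR4 fell from 20.1 ± 3.09 to 0.893 ± 0.257 CPM and IL4R from 9.89 ± 0.351 to 1.59 ± 0.278 CPM. IL10RA rose with a log2 fold change of 1.31 ± 0.27, and IL18R1 was at 0 in all 3 vector libraries and at 0.253 ± 0.113 CPM in overexpression. Of 19 immune checkpoint and exhaustion genes other than PDCD1, 8 fell and 4 rose (9 and 4 adjusted over the list alone; median -0.64; adjusted p = 0.0154; adjusted p = 0.148 with an estimated correlation). CD96 and CD226, which encode receptors of nectin-type ligands, had log2 fold changes of -2.69 ± 0.14 and -1.53 ± 0.06, and PVRIG and ENTPD1 of 0.61 ± 0.10 and 0.89 ± 0.20. The call of this list was lost with limma-voom (median -0.65, adjusted p = 0.12) and after removal of the GC and length trend (median -0.59, adjusted p = 0.0543), with medians close to the main one, in a range over all its alternatives from 0.000905 to 0.148.

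Of 30 adhesion, migration and integrin genes, 20 fell and 3 rose (20 and 4 adjusted over the list alone; median -0.65; adjusted p = 5.65e-08; adjusted p = 0.142 with an estimated correlation). PECAM1 and the integrin gene ITGA4 had log2 fold changes of -1.81 ± 0.07 and -1.08 ± 0.04, and CORO1A and ITGA1 of 0.90 ± 0.06 and 1.13 ± 0.22. Among 36 interferon-stimulated genes, 15 rose and 3 fell (16 and 3 adjusted over the list alone; median 0.46; adjusted p = 0.0154; adjusted p = 0.142 with an estimated correlation). Besides BST2, IFI35 rose with a log2 fold change of 2.49 ± 0.17, whereas ISG15 and RSAD2, also interferon-induced, fell by 1.07 and 1.48 on the log2 scale.

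Growth and metabolic genes were lower in several lists. Of 29 MYC and ribosome biogenesis genes, 23 fell and 0 rose (25 and 0 adjusted over the list alone; median -0.62; adjusted p = 3e-11; adjusted p = 0.393 with an estimated correlation), among them NCL, which encodes nucleolin, from 1366 ± 52.9 to 778 ± 14.4 CPM, and NOP56 from 370 ± 0.676 to 209 ± 5.82 CPM. Of 25 glycolysis genes, 16 fell and 4 rose (18 and 5 adjusted over the list alone; median -0.42; adjusted p = 1.5e-06; adjusted p = 0.132 with an estimated correlation). LDHA, a lactate dehydrogenase gene, fell from 863 ± 37.8 to 410 ± 6.65 CPM and PGAM1 from 487 ± 8.53 to 260 ± 4.50 CPM, while PFKL and ENO2 had log2 fold changes of 0.42 ± 0.07 and 0.40 ± 0.07. Of 21 unfolded protein response genes, 16 fell and 4 rose (median -0.27; adjusted p = 0.00058; adjusted p = 0.122 with an estimated correlation). HSPA5, the main HSP70 chaperone gene of the endoplasmic reticulum, fell from 454 ± 45.2 to 111 ± 4.87 CPM and PDIA4 by 1.03 on the log2 scale, and SEL1L and ERN1 had log2 fold changes of 0.50 ± 0.04 and 0.89 ± 0.11. Of 39 nuclear-encoded respiratory chain genes, 21 fell and 5 rose (median -0.20; adjusted p = 0.0067; adjusted p = 0.246 with an estimated correlation), with ATP5MC3 and CYC1 at -1.05 ± 0.06 and -0.9997 ± 0.05 and UQCRC2 and COX6A1 at 0.90 ± 0.05 and 0.47 ± 0.05. Of 13 mitochondrially encoded genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone; median 0.30; adjusted p = 0.0242; adjusted p = 0.518 with an estimated correlation), among them MT-ND4L and MT-CO2 at 0.86 ± 0.06 and 0.47 ± 0.04, while MT-ND1 fell by 0.34. This call was lost without vector replicate 3 (median 0.26, adjusted p = 0.0589) and after removal of the GC and length trend (median 0.14, adjusted p = 0.531), in a range over all its alternatives from 7.1e-06 to 0.531. Mitochondrial transcripts held 5.97% ± 0.059 of counts in overexpression and 4.66% ± 0.182 in vector (SD, n = 3; exact permutation p = 0.1, the smallest this design allows). The 10 most abundant genes held 6.51% ± 0.049 and 5.38% ± 0.157 (exact permutation p = 0.1, n = 3), and ribosomal protein genes 4.49% ± 0.041 and 4.46% ± 0.312 (exact permutation p = 1, n = 3).

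**Figure D2:**
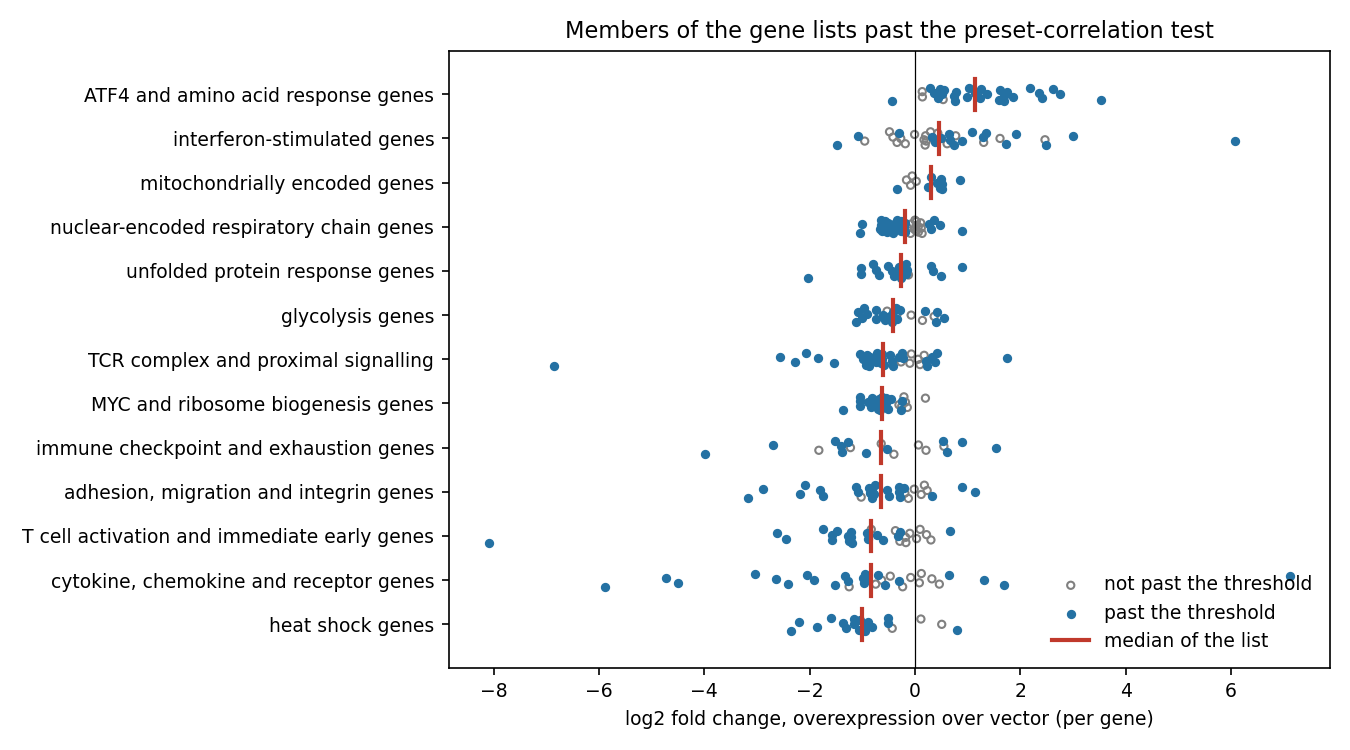
Log2 fold change of each tested member of the 13 lists past the camera test with the preset correlation; filled points passed the edgeR threshold, open points did not, and bars are list medians. The ATF4 list has a median of 1.13 and the heat shock list of -1.01.

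The remaining 21 lists did not pass camera with the preset correlation, with adjusted p from 0.05005 to 0.972. In fry, which does not compare a list with the other genes, all 13 called lists passed, with adjusted p of at most 0.0239. Several of the 21 passed fry too, among them p53 target (adjusted p = 0.00234), NF-kB (0.00341) and antigen presentation genes (0.0135). The S phase (fry adjusted p = 0.177) and ribosomal protein (0.291) lists did not. Changes of members of the 21 lists are given as log2 fold changes ± SE, or as falls on the log2 scale. Antigen presentation (11 of 22 rose, 5 fell; adjusted p = 0.05005) and p53 target genes (9 of 24 rose, 3 fell; adjusted p = 0.0503) lay nearest to the threshold. In the former, TAP2 and the immunoproteasome gene PSMB9 rose by 1.13 ± 0.07 and 1.76 ± 0.12, and PDIA3 and CANX fell by 0.75 and 0.27. In the latter, PMAIP1 and SESN2 rose by 1.496 ± 0.07 and 1.70 ± 0.13, and BTG2 and TRIAP1 fell by 1.43 and 0.89. Both calls depended on settings, with adjusted p as low as 0.0091 for antigen presentation and 0.00699 for p53 target genes when no filter was applied. Without vector replicate 2, the cytotoxic (adjusted p = 1.65e-07), G2 and M phase (0.000698), cholesterol (0.0397) and NF-kB (0.0475) lists passed as well. The T-ALL list passed without vector replicate 1 or 3 (adjusted p = 0.0405 and 0.0301), and the ribosomal protein list without vector replicate 3 (adjusted p = 0.0235). With DESeq2 and with no filter, the cytotoxic, NF-kB, T-ALL and G2 and M phase lists passed too, with upper-quartile factors and no filter the cholesterol list, without chromosome blocks the cytotoxic and T-ALL lists, after removal of the GC and length trend or with no filter the ribosomal protein list, and with no filter the hypoxia list (adjusted p = 0.0363).

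Cell cycle lists moved both ways, as did the 21055 genes tested as a whole (4768 rose and 4937 fell). Of 42 S phase genes, 9 rose, CDC45 and WDR76 among them (0.49 ± 0.04 and 0.49 ± 0.06), and 14 fell, RRM1 and BLM among them (-0.39 ± 0.04 and -0.39 ± 0.05). Of 53 G2 and M phase genes, 9 rose, including HMGB2 (0.94 ± 0.08) and UBE2C (0.81 ± 0.09), and 20 fell, including CENPF (-0.90 ± 0.07) and TUBB4B (-0.68 ± 0.04); adjusted over the list alone, 10 rose and 20 fell. Of 26 FOXO and quiescence genes, 7 rose and 12 fell: CDKN1B and TXNIP rose by 1.14 ± 0.08 and 2.16 ± 0.21, and BTG2 and BTG1 fell by 1.43 and 0.92. Of 32 apoptosis regulators, 4 rose and 8 fell, with PMAIP1 and CASP9 (0.51 ± 0.10) rising and BCL2L11 and XIAP falling by 1.16 and 0.59. Of 24 NF-kB target genes, 2 rose, ICAM1 (1.06 ± 0.22) and TNIP1 (0.19 ± 0.05), and 9 fell, among them CD83 and NFKB1 by 1.02 and 0.56. The TNIP1 call was lost without overexpression replicate 2 or 3 and without vector replicate 1 or 3, with adjusted p of 0.0771, 0.0773, 0.0633 and 0.0717, and with DESeq2 (adjusted p = 0.0622) and no filter (adjusted p = 0.0601). Of 17 cytotoxic effector genes, 3 rose and 7 fell (4 and 7 adjusted over the list alone), with ZEB2 and GZMH at 4.10 ± 0.40 and 2.49 ± 0.41 and LAMP1 and CTSC at -0.90 ± 0.05 and -0.91 ± 0.06. Of 30 regulators of T-ALL and thymocytes, 7 rose and 14 fell (8 and 17 adjusted over the list alone), with BCL11A and IKZF1 rising by 1.09 ± 0.06 and 0.39 ± 0.05 and BCL11B and HES4 falling by 0.82 and 1.87. Of 76 cytosolic ribosomal protein genes, 12 rose and 24 fell, RPL36 at 0.34 ± 0.06 and RPS29 at -0.71 ± 0.06. Of 23 hypoxia-induced genes, 3 rose and 10 fell, with VEGFA at 2.41 ± 0.38 (3.10 without vector replicate 2), AK4 at 1.29 ± 0.25, KDM3A at -0.75 ± 0.05 and EGLN1 at -0.95 ± 0.07. Of 24 cholesterol synthesis genes, 9 rose and 4 fell, with FDFT1 and SREBF2 at 0.51 ± 0.04 and 0.44 ± 0.04 and SQLE at -0.28 ± 0.06.

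Of 15 TGF-beta and matrix genes, 3 rose and 7 fell (4 and 7 adjusted over the list alone), with LAMB1 and SPARC at 0.70 ± 0.07 and 1.19 ± 0.24 and THBS1 and LOXL2 at -3.18 ± 0.26 and -1.500 ± 0.14. Of 14 replication-dependent histone genes, 5 fell and 0 rose (4 and 0 adjusted over the list alone), H2AC6 and H1-2 by 1.65 and 2.08. Of 7 nuclear-retained and small structural RNAs, 3 rose and 2 fell, with MALAT1 at 1.82 ± 0.08, RN7SL1 at 2.68 ± 0.49 (3.36 without vector replicate 2), NEAT1 at -1.55 ± 0.12 and RPPH1 at -4.50 ± 0.76 (-5.16 without overexpression replicate 3 and -5.83 with limma-voom).

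Markers of other cell types passed the expression filter in part, from 3 of 11 natural killer cell markers to 8 of 16 epithelial and kidney line markers. Of 5 B cell markers tested, 1 rose and 2, BLK and CD79A, fell, CD79A by 0.62 (not called without overexpression replicate 1 or 3, adjusted p = 0.0574 and 0.0568). Of 5 myeloid markers, AIF1 and CD14 fell by 0.52 and 2.91 (CD14 -3.52 without overexpression replicate 1). Of 3 natural killer cell markers, NCAM1 rose by 2.38 ± 0.66, or 3.41 without vector replicate 2, and was not called without overexpression replicate 1 or 2 or vector replicate 1 (adjusted p = 0.0597, 0.0595 and 0.0611). The median of that list was -0.74, its mean 0.17 and the direction of its camera test up. Of 6 erythroid and megakaryocyte markers, EPOR and ITGA2B rose by 0.73 ± 0.12 and 1.13 ± 0.25, and the near-identical alpha globin genes HBA1 and HBA2 fell by 6.07 and 5.98 (4 rose and 2 fell adjusted over the list alone; median 0.80, mean -1.36, camera direction up). HBA1 had 1178, 74 and 1164 estimated counts in vector, and with limma-voom neither globin gene was called (log2 fold changes -4.99 and -4.80, adjusted p = 0.222 and 0.232). Of 8 epithelial and kidney line markers, 3 rose, among them ESRP1 and KRT8 by 1.96 ± 0.15 and 1.74 ± 0.42, and CDH2 and LHX1 fell by 0.37 and 1.74 (LHX1 -2.36 without overexpression replicate 2). Of 4 fibroblast and endothelial markers, COL1A1 and CLDN5 fell by 0.86 and 0.72. The LHX1 call was lost when any library but overexpression replicate 2 was left out, and the CLDN5 call when any but vector replicate 1 was, with adjusted p of up to 0.123 and 0.118; both were also lost with DESeq2 (adjusted p = 0.0892 and 0.119) and with no filter (adjusted p = 0.0733 and 0.0968), and CLDN5 with upper-quartile factors (adjusted p = 0.06) and after removal of the GC and length trend (adjusted p = 0.106).

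Along the chromosomes, genes of chromosome 9 were lower together, with a median log2 change of -0.40 over 459 genes, 78.0% of them below 0, and genes of chromosome 2 had a median of -0.31 over 788 genes. In all, 33 of 281 windows were shifted, against at most 4 in 100 shufflings of the genes, which do not keep neighbours together. Rotations of the gene order, which do, gave some chromosome a median as far from 0 as that of chromosome 9 or 2 often enough for permutation p of 0.14 and 0.799 over 1000 rotations. These rotations carry the low genes of chromosomes 9 and 2 themselves onto other chromosomes. Neighbouring shifted windows formed blocks on chromosome 1 (193090866 to 248919946, median -0.43), chromosome 2 (85602856 to 176338025, -0.37), chromosome 4 (144831908 to 189963204, 0.40) and chromosome 9 (71683366 to 127735317, -0.38, and 129094810 to 137870016, -0.53; hg38). Chromosomes 2 and 9 and these blocks held 2273 of the tested genes (10.8%) and 1274 of the called ones.

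**Figure D3:**
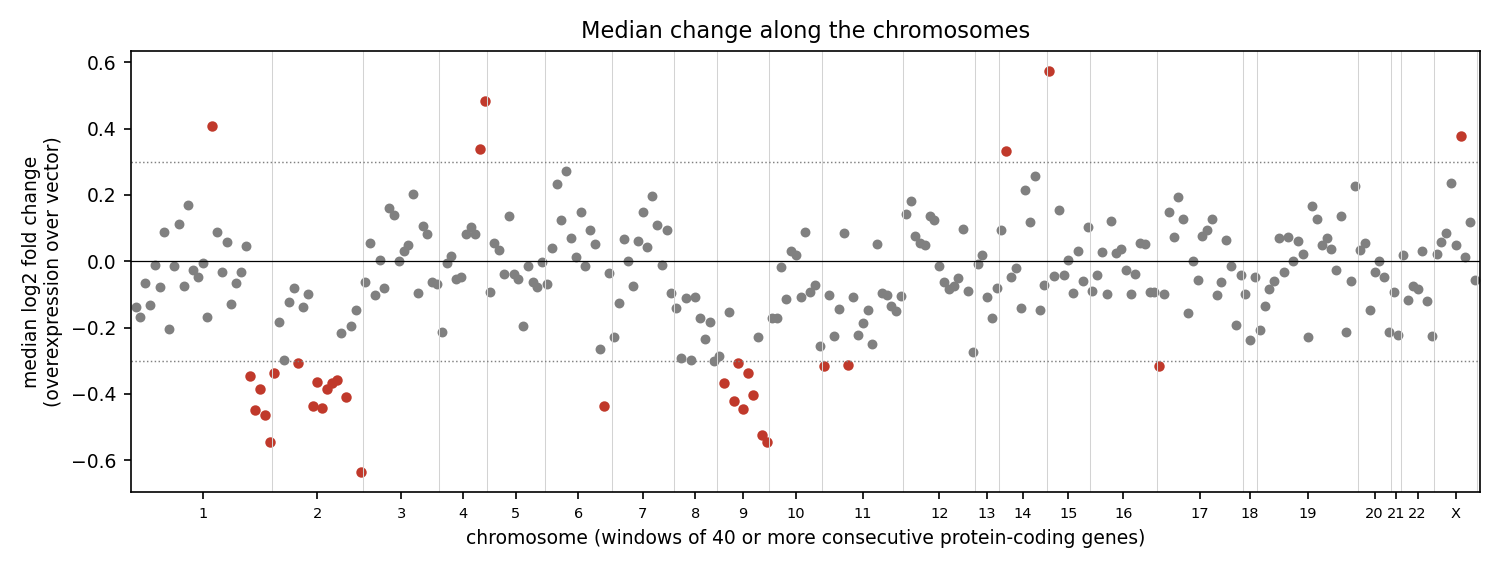
Median log2 fold change of overexpression over vector in 281 windows of consecutive protein-coding genes, in chromosome order; coloured points lie at least 0.3 from 0 (dotted lines). Windows of chromosome 9 lie mostly below 0, where the chromosome as a whole has a median of -0.40.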

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

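The counts of higher and lower genes held within 1.5 times under each alternative test, scaling and filter; a size threshold of at least 2-fold left 1766 higher and 1310 lower genes by construction, and 1090 and 814 together with the stricter filter, which tests fewer genes. With 1 library left out, 3741 to 5292 genes were higher and 4175 to 5576 lower. Among these fits, only that without vector replicate 2 called more genes than the main fit (10868 against 9705). In each of these fits none of the original calls changed sign. Removal of the GC and length trend turned 21 of them. Like the division by 4 and the removal of chromosome blocks, that removal was chosen after seeing the data. The PDCD1 change stayed between 5.85 and 6.10 wherever it could be fitted; removal of chromosome blocks takes out all of chromosome 2 and PDCD1 with it. The number of lists past the threshold was 13, and 1 with an estimated correlation. It was 22 with no filter, where many weakly expressed genes enter the comparison. The cause of neither change was tested. Same-numbered libraries did not deviate together (residual correlations 0.00521, 0.00125 and 0.023); with the replicate block 4217 genes were higher and 4473 lower and 14 lists passed, antigen presentation among them (adjusted p = 0.0314), while the TNIP1, LHX1 and CLDN5 calls were lost. For 4 uncalled lists the direction of the camera test turned in some settings, the cause not tested; list medians, given in parentheses, mostly kept their sign. The natural killer list (3 members, median -0.74 with an upward test) turned to a downward test with DESeq2 (-0.98), limma-voom (-0.62), upper-quartile factors (-0.68), no filter (-0.96) and the GC and length trend removed (-0.91), and in leave-one-out fits with medians from -2.48 to -0.71. The test of the erythroid list (median 0.80) turned with the replicate block (0.76), without vector replicate 2 (0.81; 0.66 to 0.81 with any 1 library left out) and, its median included, with DESeq2 (-2.16) and no filter (-2.12); with the stricter filter the median was -2.61 and the test kept its direction. The test of the S phase list (-0.067) turned with upper-quartile factors (-0.0197), and that of the apoptosis list (-0.035), median included, without chromosome blocks (0.0183). With the stricter filter 3 lists, and with values divided by 4 a total of 2, kept too few members to test. The pseudocount alternative applied only to normalized values and was not run. The unit of the estimates, which is not settled, limits what can be said of genes near 12 estimated counts.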

Other observations

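In this part, the tests of chromosome 9 for scaling, few genes, neighbouring genes and copy number were chosen after the result was seen, as were the gene families. Cancer-testis antigen genes of chromosome X, 1 of 5 families counted, mostly rose. Of 21 tested, 18 rose and 2 fell, with a median log2 change of 4.93. Without the 4 already seen among the largest changes or near 0 in 1 group, 14 of 17 rose and 2 fell, with a median of 4.82. Members of families were matched by symbol. In both counts, 1 of the 2 that fell, MAGEA4-AS1, is an antisense RNA and not an antigen gene. The families were picked with values per gene in view, so no p value is given for them, and paralogs share reads, so members are not independent. MAGEA12 had means of 705 estimated counts in overexpression and 28.3 in vector, whereas MAGEA4 went the other way, from 1334 to 67.3. Of 10 protocadherin genes of chromosome 5, 7 fell and 0 rose, and of 17 S100 and annexin genes, 7 rose and 1 fell. Of 15 serpin genes, 6 rose and 1 fell. In 218 genes of chromosome 19 with a zinc finger symbol, 48 rose and 48 fell. Antisense RNAs such as ZNF566-AS1 and pseudogenes such as ZNF137P are among the latter family. Outside each family, 22.6% to 22.7% of tested genes rose and 23.4% to 23.5% fell. The zinc finger counts lie near these shares.

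Genes of chromosome 9 were lower together in overexpression. A GC or length trend is argued against: the median of chromosome 9 was -0.36 after removal of that trend. The median lay -0.36 from that of the other autosomes, and 78.0% of its genes were below 0. With TMM scaling and a median of -0.40 over 459 genes, both of these outcomes were known in advance. They describe the pattern and are no independent test of scaling or of a few genes. A candidate explanation is a different number of copies: each arm and each class of its genes by expression (low, middle and high) had a median of -0.30 or lower (log2 of 3 over 4 is -0.415). Chance placement of neighbouring genes is not excluded. Some chromosome had a median as far from 0 often enough for a permutation p of 0.1399 over 1000 rotations of the gene order. In this test the low genes of chromosome 9 themselves land on small chromosomes. A second measure was computed after that p was known. It found a median as far from 0 in 0 of 10771 stretches of as many genes outside chromosome 9. Neighbouring stretches shared almost all their genes, and stretches could run across chromosome ends. Their number therefore far exceeds that of independent stretches, and the count does not outweigh the permutation p of the rotations. No DNA was measured here.

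The ATF4 list was higher and the heat shock list lower with the preset correlation, and with an estimated one the heat shock list kept its call (adjusted p = 0.0242) and the ATF4 list lost it (adjusted p = 0.0513). Neither followed a GC content or length trend, with medians of 1.06 and -1.002 once it was removed, nor chromosomes 2 and 9 and the shifted blocks elsewhere, with medians of 0.99 over 27 and -0.98 over 17 members outside them. An effect of the isoform may account for both changes, as may other differences between the cell populations or their culture, and the design leaves these open.

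Near-absence in 1 group was seen for 28 called genes with a mean under 12 estimated counts in it and at least 200 in the other, 8 in vector (ABCC8, TNN and ZFP92 among them) and 20 in overexpression (BLK, CD40LG and LTA among them), named after their values were seen. Of 23 with a position, 3 lay on chromosomes 2 and 9 or in the shifted blocks elsewhere (13.04%, upper exact 95% bound 33.6%). Of all placed tested genes 13.28% lay there, so these genes were not seen to concentrate in them. Block medians from -0.53 to 0.40 on the log2 scale are too small to bring a gene near 0. The share therefore cannot test copy number as a source, and losses of single genes were not examined. The highest level of LYZ, HBB, MS4A1, GNLY and COL1A2 in any library was 0.414 CPM. Each was taken as an abundant transcript of 1 type, in order myeloid, erythroid, B, natural killer and fibroblast cells. This argues against such cells in 1 group only as far as they express these genes. Erythroid cells are not settled, since HBA2, itself near 0 in overexpression, had 15.4, 0.632 and 13.4 CPM in vector. Cells of other types, epithelial or kidney line cells included, were not tested in this way. Different clones in the groups may carry such differences, a hypothesis that was not tested, and an effect of the isoform stays open as well.

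The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. Each split but the real one mixes libraries of both groups. The group difference then enters its spread within groups, and part of that difference stays in its contrast. The counts of these splits are therefore no measure of chance, and no conclusion is drawn from them. As many genes were higher, and as many lower, in 1 split, the real one, with 4768 and 4937 genes against at most 0 in the others (edgeR). For gene lists past the threshold, 3 of the 10 splits gave as many as the real 13, and the highest of the others gave 14.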
